A study of Mus musculus with 53 samples.

How the data were processed

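RNA was measured in 53 libraries from the medial prefrontal cortex (mPFC) and the central nucleus of the amygdala (CeA) of C57BL6/J mice at postnatal day 119, per the labels' characteristics. Per the labels' protocols, mPFC was dissected fresh and frozen, CeA was punched from frozen slices of 300 µm, RNA was isolated with Trizol and MagMAX, and 1 µg of total RNA was fragmented and copied into cDNA with a template-switching oligonucleotide before a pair of PCR rounds. The mPFC libraries and the CeA libraries were read single-end on different Illumina instruments, per the labels' protocols, so region and instrument cannot be separated. Whether the degenerate bases of the switching oligonucleotide were used to remove duplicate reads, and whether counting used strand, is not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain, and intervals from counts cover counting error only.

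The values used are the authors' deposited counts, whole numbers of reads per Ensembl gene with no normalization, 1 library per sample. Per the submitters' processing notes, the tools were FastQC 0.11.8, Bowtie2 2.3.4.3, HTSeq 0.11.0, DESeq2 1.10.1 and R 3.5.1, with the mouse build mm10 (GRCm38.p6); the order and settings of these steps are not given in the sources used here. The CeA counts cover 56350 gene identifiers and the mPFC counts 54547, of which 54393 are in both, so the regions were counted with different annotation releases. Symbols came from a GENCODE annotation of GRCm38, which matched 55394 identifiers in CeA and 53620 in mPFC. The 92 spike-in entries and the 5 summary entries for reads in no gene stayed out of library sizes and tests. Reads counted in genes made up 71.6% to 73.4% of all reads in CeA and 74.1% to 75.5% in mPFC.

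Counts in genes ranged from 1062443 to 1968971 per library in CeA and from 1531574 to 2607438 in mPFC. At this depth counts were simulated from the real libraries' means and sizes. Their spread was the trend over expression level, without each gene's own spread. Genes changed by 1.25, 1.5, 2 and 4-fold, 50 at each fold size, entered together and gave the following recovery. For the diet effect in non-dependent CeA, 88% of 2-fold and 42% of 1.5-fold changes were recovered over 11579 genes. For the same effect in mPFC these were 98% and 72% over 12213 genes. For the dependence effect on control diet they were 94% and 64% in CeA over 11579 genes, and 98% and 68% in mPFC over 12227 genes. The real dependence comparisons on control diet called 0 genes in CeA and 1 in mPFC. The adjusted threshold is stricter where few genes change, so recovery there can be lower than in the simulation. False calls made up between 0.833% and 6.47% of the calls in the 8 simulated comparisons.

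Groups came from the labels' chow and ethanol entries, which give 8 groups of region, diet and drinking history. Replicate numbers are the mouse numbers of the labels. The same number in both regions was taken to mark the same mouse where diet and history also match, since per the labels' protocols both regions were taken from each brain. The labels do not state it for single libraries. The numbers so pair libraries between regions but not within one, and there were 15 such pairs. Number 16 is labelled control diet in CeA and PLX5622 in mPFC and was never paired. As a check, the correlation over genes of the deviations of the 2 libraries of a pair ran from -0.0356 to 0.0792 over the 15 pairs, with a median of 0.0165, so the values themselves do not show the pairing. Pairs of libraries within a group differed by more than counting noise in every case, with a chi-square per gene of 1.11 or more where 1 is expected from noise, so no library was counted as a duplicate.

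The main test was edgeR 4.0.16 in R 4.3.3, a two-sided quasi-likelihood F test with TMM factors, filterByExpr (minimum count 10, minimum total 15) and robust spread, with 1 coefficient per group. All 4 groups of a region entered 1 fit, and all 8 groups 1 fit for the comparisons between regions. It tested 11721 genes in CeA, 12331 in mPFC and 13035 in the joint fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors of log2 fold changes were the fold change over the square root of F. Group levels are CPM, counts per 1e6 of TMM library size, as mean ± SD. A group at 0 counts was set against a floor of 3 counts over the group, and ratios with 1 to 3 counts are given with an exact 95% counting interval.

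Before the data were examined, the samples, the fits, the alternatives and 36 gene lists of cell types and pathways were fixed, as was the rule for the genes named. In each comparison within a region the rule took up to 6 genes that rose and 6 that fell with the smallest p, in diet comparisons also those outside the microglia and macrophage lists, up to 3 members of each list with a call, 2 members of other lists as values, and Csf1r, P2ry12, Tmem119, Cx3cr1 and Aif1 in diet comparisons. Where nothing passed, the 5 smallest p are given as values. Between regions it took 8 in each direction. Lists were tested in edgeR with camera, which compares a list with all other genes, at a preset correlation of 0.01, over 310 tests of lists with at least 5 members and 10 comparisons. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were run beside it. At the preset correlation 73 of the 310 tests passed, with an estimated correlation 11 of these held, and fry passed 15. The lists described are a choice from those with calls or a small p. The mean log2(CPM + 1) of a list per library, over members with a mean CPM of 1 or more, was compared by an exact two-sided permutation test for 3 lists (homeostatic microglia, pan-myeloid, border macrophage) in 8 comparisons, adjusted over these 24.

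The alternatives fixed in advance were DESeq2 1.42.0, its size factors, no filter on low counts, a filter at a mean CPM of 5, 1 surrogate variable (sva 3.50.0), only the 2 groups compared, each library left out, the mouse as a block (edgeR, or limma 3.58.1 voom), the 2 libraries numbered 16 left out, and for lists other pseudocounts, members and tests. Chosen after seeing the data were leaving out the libraries with added spike-in RNA, and covariates for the presence of spike-in RNA, for striatal neuron genes and for long genes, as well as the mean dependence effect over both diets. Added spike-in RNA was taken as over 1000 spike-in counts. Positions are those of the GRCm38 annotation. Figures were drawn with matplotlib 3.10.9.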

Results

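Transcripts were counted by sequencing biased to the 3' ends of RNA from whole tissue of 2 brain regions, the medial prefrontal cortex (mPFC) and the central nucleus of the amygdala (CeA). Mice received control chow or chow with PLX5622 at 1200 mg/kg, an inhibitor of the receptor CSF1R on which microglia depend for survival, for 28 days before the ethanol phase. In that phase drinking of 15% ethanol was paired with chronic intermittent ethanol exposure over 4 weeks, and tissue was taken 24 hours after the last exposure. Mice are labelled dependent or non-dependent, and what the non-dependent mice received beyond that label is not given in the sources used here. In CeA there were 6 control non-dependent, 4 PLX5622 non-dependent, 5 control dependent and 4 PLX5622 dependent mice. In mPFC there were 7 control non-dependent and 9 in each other group. Counts in genes ranged from 1062443 to 1968971 per CeA library (median 1404282) and from 1531574 to 2607438 per mPFC library (median 2022324), with 16674 to 18362 and 17022 to 18317 genes detected. Synthetic spike-in RNA was present in 12 libraries, all from dependent mice (3 in each of the 4 dependent groups), with at least 11745 counts in CeA and 21989 in mPFC. The other libraries held 316 or fewer.

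The first question was how far PLX5622 removed microglial transcripts from each region, and whether drinking history changed this. Homeostatic microglia genes were lower in every PLX5622 library than in every control library of the same region and history. In CeA their mean log2(CPM + 1) was 1.54 ± 0.20 (SD, n = 4) with PLX5622 and 3.65 ± 0.12 (n = 6) without in non-dependent mice (exact two-sided permutation p = 0.00476, adjusted p = 0.0143), and 1.51 ± 0.11 (n = 4) against 3.69 ± 0.07 (n = 5) in dependent mice (exact permutation p = 0.00794, adjusted p = 0.0173). In mPFC it was 1.66 ± 0.11 (n = 9) against 3.83 ± 0.03 (n = 7), exact permutation p = 8.74e-05, and 1.69 ± 0.25 (n = 9) against 3.83 ± 0.08 (n = 9), exact permutation p = 4.11e-05. The pan-myeloid list, with the complement and Fc receptor genes that microglia share with other macrophages, differed by -1.93 and -2.02 on the log2 scale in CeA and by -2.06 and -2.10 in mPFC. Border macrophage genes, marking macrophages of the meninges and vessels, fell by 0.55 in CeA of non-dependent mice (exact permutation p = 0.0238, adjusted p = 0.0440), and differed by -1.01 in CeA of dependent mice and by -0.97 and -1.06 in mPFC. With a pseudocount of 0.25 the first of these was -0.79, with an exact permutation p of 0.0667. In CeA of dependent mice control library 2 had a mean of 3.07, against 1.49 to 1.63 in the other control libraries. Leaving out 1 library at a time there gave differences from -1.10 to -0.71. The means cover 11 members in CeA, of which 1 had enough counts for the test over all genes, at -0.072 in non-dependent and -0.025 in dependent mice. Drinking history was not detected to shift the homeostatic list, with differences of 0.04 and -0.03 in CeA on control and PLX5622 diet (exact permutation p = 0.532 and 0.857) and of 0.00 and 0.03 in mPFC (exact permutation p = 0.980 and 0.805).

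**Figure D1:**
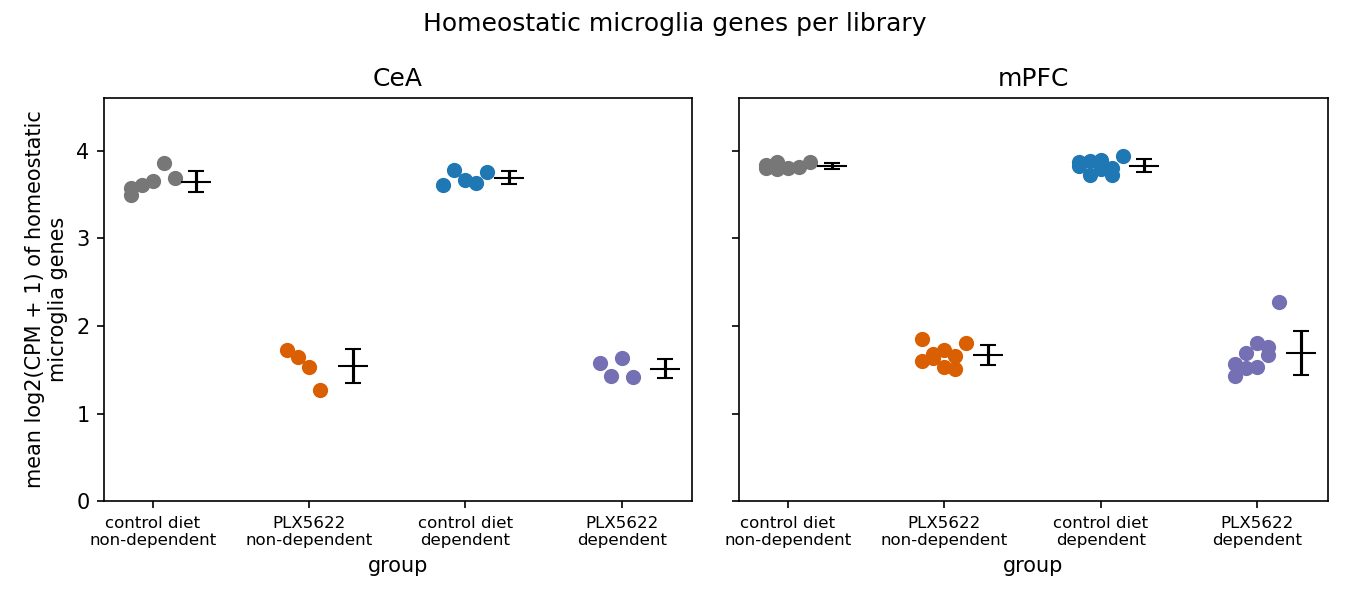
Mean log2(CPM + 1) of the homeostatic microglia genes in each library (points, with group mean and SD), by group in CeA (left) and mPFC (right). Group means lay between 1.51 and 1.69 with PLX5622 and between 3.65 and 3.83 without, with no overlap of libraries.

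In CeA of non-dependent mice PLX5622 removed most transcripts of the genes that define microglia. Csf1r (chromosome 18, 61100598 to 61132149, GRCm38), which encodes the drug's target, fell from 48.0 ± 6.37 CPM (SD, n = 6) to 1.36 ± 0.07 (n = 4), a log2 fold change of -5.06 ± 0.27 (SE). The purinergic receptor gene P2ry12 (chromosome 3, 59216272 to 59262871) fell by 3.69 ± 0.30, as did the fractalkine receptor gene Cx3cr1 (chromosome 9, 119901616 to 120069879) at -3.15 ± 0.25, the protease gene Ctss at -3.76 and the complement gene C1qb at -5.02. Tmem119 (chromosome 5, 113793729 to 113800516), a microglial surface marker, had 2 counts over the PLX5622 libraries, 71.3 times below control with a 95% counting interval of 19.5 to 593. Of the 20 homeostatic microglia genes tested 16 fell, 20 when adjusted over the list alone (camera adjusted p = 1.31e-09 with an estimated correlation), and of 17 pan-myeloid genes 12 fell, 14 adjusted over the list alone (camera adjusted p = 6.81e-08 with an estimated correlation). Outside these lists fell genes known from immune cells, among them the prostaglandin D synthase gene Hpgds at -4.15, the Rac activator Dock2 at -2.74 and the related Dock8 at -2.76. The adaptor gene Fyb and the perforin-like Mpeg1 had 2 counts each with PLX5622, 26.6 and 28.7 times below control with intervals of 7.11 to 223 and 7.69 to 241. Arhgap45 had 3 counts, 18.9 times below with an interval of 6.24 to 93.5. Il6ra, the interleukin-6 receptor and 1 of the inflammatory signalling genes, fell by 1.13 ± 0.24, a call lost in 1 of the 19 fits without 1 library.

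The same comparison in CeA held 50 genes that rose, by a median of 0.38 on the log2 scale. Fam155a (chromosome 8, 9205902 to 9771161), a subunit of a neuronal sodium leak channel, rose from 907 ± 130 CPM (n = 6) to 1338 ± 75.6 (n = 4), a log2 fold change of 0.56 ± 0.08. The secreted-protein gene Nell1 rose by 0.43 ± 0.08, the glycosyltransferase gene Galnt18 by 0.50, the glutamate receptor scaffold Grip1 by 0.47 and the oxidoreductase gene Wwox by 0.47. Grm8, a metabotropic glutamate receptor and the only 1 of 38 glutamate receptor and synapse genes to rise (3 adjusted over the list alone; camera adjusted p = 0.00812, and adjusted p = 0.393 with an estimated correlation), rose by 0.40. Kcnma1, the calcium-activated potassium channel that ethanol opens, rose by 0.30 (edgeR adjusted p = 0.0402), a call lost in 8 of the 19 fits without 1 library. The genes that rose spanned a median of 569 kb, against 29.3 kb for all genes tested, and 47 of the 50 spanned 100 kb or more. Genes of that span took 38.8 ± 0.38% of counts (SD, n = 4) with PLX5622 and 36.6 ± 1.61% (n = 6) in control non-dependent libraries. In dependent mice they took 38.2 ± 0.72% (n = 5) on control diet and 38.1 ± 0.72% (n = 4) with PLX5622. The control non-dependent group was thus the lowest of the 4. Without control library 17 of this group 24 genes rose and without control library 19, 33. Without PLX5622 library 23, 19 rose, and without PLX5622 library 47, 25, whereas 73 rose without control library 20. With 1 surrogate variable 27 rose and with only these 2 groups 21, while more than 50 rose with no filter on low counts.

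No member of 3 further lists passed here, although camera at the preset correlation called them. All 13 striatal neuron genes lay below 0 (median -1.17; camera adjusted p = 1.24e-07, and adjusted p = 0.503 with an estimated correlation), with the dopamine signalling gene Ppp1r1b at -1.03 ± 0.42. Oligodendrocyte genes had a median of -0.38 over 22 (adjusted p = 5.77e-09, and 0.485 with an estimated correlation), with the myelin regulator Myrf at -0.68. Meninges and choroid plexus genes had a median of 0.68 over 15 (adjusted p = 0.000471, and 0.60 with an estimated correlation), with Mgp at 0.68. In all, edgeR called 0.913% of 11721 genes, 50 up and 57 down. Without PLX5622 library 23 the count was 71 and without PLX5622 library 47 it was 70.

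**Figure D2:**
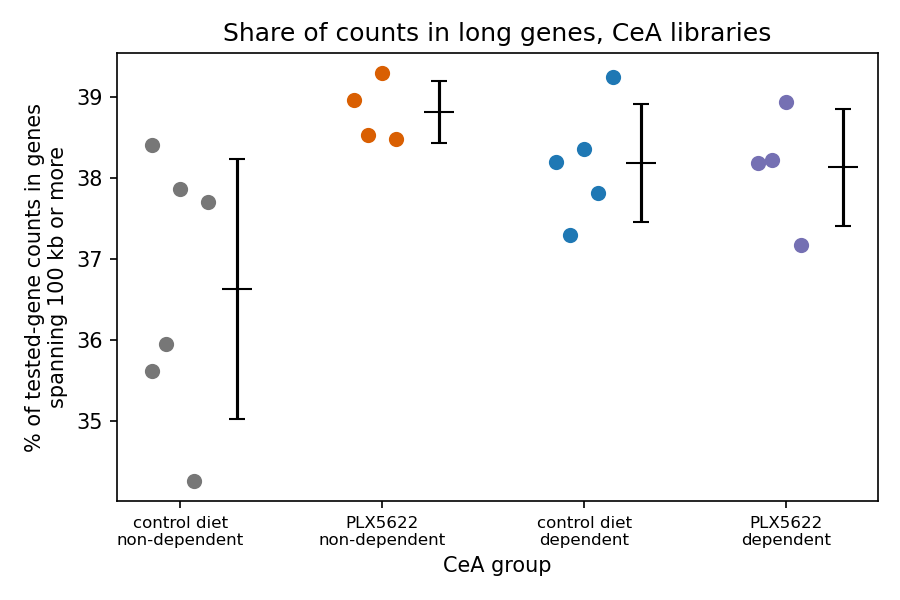
Percent of the counts of tested genes that fell in genes spanning 100 kb or more, for each CeA library (points, with group mean and SD), by group. Control non-dependent libraries had the widest range, 34.3% to 38.4%, against 38.5% to 39.3% in PLX5622 non-dependent libraries. Dependent libraries ran from 37.3% to 39.3% on control diet and from 37.2% to 38.9% with PLX5622.

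In CeA of dependent mice microglial genes fell with PLX5622, and 1 gene rose. Csf1r fell from 54.3 ± 4.95 CPM (SD, n = 5) to 1.86 ± 1.53 (n = 4), a log2 fold change of -4.76 ± 0.26, as did Ctss at -4.76 ± 0.25, Laptm5, a lysosomal gene of blood-derived cells, at -4.69, Cx3cr1 at -3.25, P2ry12 at -3.86 and C1qb at -4.67. Selplg and Tmem119 had 3 counts each, 43.3 and 40.8 times below control with intervals of 14.6 to 212 and 13.7 to 200. Of 20 homeostatic microglia genes 16 fell, 20 adjusted over the list alone, and of 17 pan-myeloid genes 11, 14 adjusted over the list alone (camera adjusted p = 1.31e-09 and 2.73e-08 with an estimated correlation). Outside the lists fell the Src-family kinase gene Lyn at -2.21, Hpgds at -3.47 and Il6ra at -1.72. Arhgap45 had no counts, at least 11.9-fold lower than control for a floor of 3 counts over the group. Tcea2, a transcription elongation factor, rose by 0.74 ± 0.18 (edgeR adjusted p = 0.0460), a call lost in 13 of the 19 fits without 1 library and with DESeq2 (adjusted p = 0.294). Striatal neuron genes had a median of -0.47 and oligodendrocyte genes of -0.31, with no member past the threshold (camera adjusted p = 0.812 and 0.652 with an estimated correlation). Interferon response genes had a median of -0.43 over 8 (adjusted p = 0.00130, and 0.47 with an estimated correlation), with H2-K1 at -1.06 ± 0.40. In all 48 of 11721 genes passed, 1 up and 47 down. Without the libraries holding spike-in RNA, which leave 1 PLX5622 library that is assumed to vary like the rest, 21 passed.

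In mPFC of non-dependent mice PLX5622 removed microglial transcripts as well. Csf1r fell from 38.0 ± 5.05 CPM (SD, n = 7) to 1.45 ± 0.93 (n = 9), a log2 fold change of -4.67 ± 0.21, as did P2ry12 at -4.16 ± 0.17, Cx3cr1 at -3.41, Tmem119 at -3.26, Selplg at -4.56 and the signalling adaptor Tyrobp at -4.93. Of 21 homeostatic microglia genes 19 fell, 20 adjusted over the list alone, and of 17 pan-myeloid genes 15, 16 adjusted over the list alone (camera adjusted p = 1.28e-21 and 2.08e-17 with an estimated correlation). The lysozyme gene Lyz2 fell by 2.90, the only 1 of 14 activated microglia genes to do so, and F13a1, a coagulation factor made by border macrophages, was at -2.54. Outside the myeloid lists fell Mpeg1 at -4.17, Hpgds at -3.39, Fyb at -4.01 and Cd33, which had 1 count with PLX5622, 98.8 times below control with an interval of 17.2 to 3954. Inflammatory signalling genes fell in 2 of 13 cases, the RNA-sensing receptor Tlr7 at -3.45 and Il6ra at -1.21 (camera adjusted p = 0.0323, and adjusted p = 0.175 with an estimated correlation). The matrix glycoprotein gene Sparc fell by 0.64 ± 0.12.

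Smaller differences accompanied these in mPFC of non-dependent mice. Cog7, a Golgi trafficking subunit and the only gene to rise, rose by 0.38 ± 0.09 (edgeR adjusted p = 0.010), a call lost in 1 of the 34 fits without 1 library. B2m, the light chain of class I histocompatibility molecules, fell by 0.29 and Prkcd, a kinase of central amygdala neurons, was at -1.05, calls lost in 9 and 11 of these fits. Cholesterol synthesis genes lay above 0 in 20 of 22 cases (median 0.15; camera adjusted p = 8.52e-05, and adjusted p = 0.154 with an estimated correlation), with Stard4 at 0.25 ± 0.08 and none past the threshold over all genes. Ethanol metabolism and antioxidant genes had a median of 0.065 over 19 (adjusted p = 0.0156, and 0.0953 with an estimated correlation), with the glutathione transferase Gstm1 at 0.25 ± 0.07. Camera at the preset correlation, given here with DESeq2 size factors, also called astrocyte genes (adjusted p = 0.00158) and meninges and choroid plexus genes (0.00509), both up. Neither list passed with an estimated correlation. In all edgeR called 78 of 12331 genes, 1 up and 77 down, DESeq2 a number equal to 1.18% of these genes, and edgeR 50 among genes with a mean CPM of 5 or more.

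In mPFC of dependent mice microglial genes fell, along with many genes that changed little. Csf1r fell from 41.8 ± 3.21 CPM (SD, n = 9) to 1.70 ± 1.66 (n = 9), a log2 fold change of -4.58 ± 0.19, as did P2ry12 at -3.83 ± 0.16, Cx3cr1 at -3.11, Tmem119 at -3.66, Siglech at -4.74 and Laptm5 at -4.63. Of 21 homeostatic microglia genes 19 fell, 20 adjusted over the list alone, and of 17 pan-myeloid genes 16, as many as when adjusted over the list alone (camera adjusted p = 3.66e-23 and 1.46e-18 with an estimated correlation). Outside the myeloid lists fell the macrophage marker Adgre1 at -3.63 and the organic anion transporter Slco2b1 at -2.03. Of 14 activated microglia genes 3 fell, Lyz2 at -2.61, the lysosomal protease Ctsz at -0.47 and the tetraspanin Cd9 at -0.56 (camera adjusted p = 0.0132, and adjusted p = 0.175 with an estimated correlation). Tlr7 and Il6ra, at -2.55 and -1.17, were the 2 of 13 inflammatory signalling genes that fell (adjusted p = 0.0232 with an estimated correlation). Sparc fell by 0.58 ± 0.11, B2m lay at -0.31 ± 0.07 and Kctd12, a subunit of GABA-B receptors, at -0.47 ± 0.12, the last call being lost in 22 of the 34 fits without 1 library. The genes that rose did so by little, among them Snn by 0.18, the kinase Map2k1 by 0.15, Naa38 by 0.23, Avpi1 by 0.34 and the mitochondrial dehydrogenase Aldh6a1 by 0.33, calls lost in 5, 11, 11, 12 and 21 of these fits. With only these 2 groups 0 genes rose, and 0 without the libraries holding spike-in RNA. In all edgeR called 0.916% of 12331 genes, 6 up and the others down, and DESeq2 181 genes, with 72 called by edgeR when only these 2 groups entered and 74 among genes with a mean CPM of 5 or more.

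**Figure D3:**
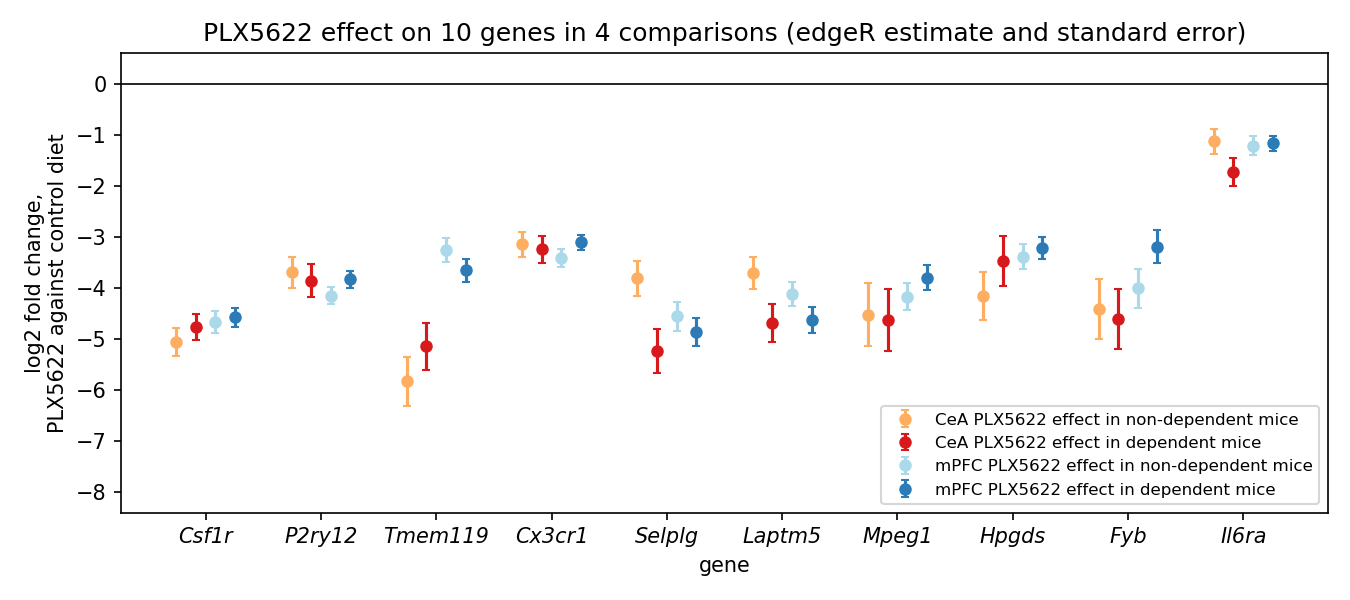
Log2 fold change of PLX5622 against control diet (edgeR estimate with standard error, vertical axis) for 10 genes in the 4 diet comparisons. Csf1r lay between -5.06 and -4.58 in all 4 comparisons and Il6ra between -1.72 and -1.13.

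The loss overlapped between the diet comparisons. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.585 (jackknife SE 0.0833) between non-dependent and dependent mice in CeA and r = 0.768 (SE 0.0355) in mPFC, comparisons that share no library. Without the microglia and macrophage lists these were 0.376 and 0.55. In CeA 42 genes fell in both, against 0.229 for independent lists, and in mPFC 71, against 0.668. Between regions r was 0.608 in non-dependent and 0.654 in dependent mice (0.335 and 0.384 without these lists), with 47 and 46 genes falling in both regions. Of the genes that fell in at least 1 comparison, 41 fell in all 4, of which 26 belong to the microglia and macrophage lists. Aif1, the gene of the microglial protein IBA1, had too few counts to be tested, with 26 and 28 counts in the non-dependent and dependent control groups of CeA, 6 and 4 in the PLX5622 groups, and 27, 41, 12 and 10 in mPFC.

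The next question was what ethanol dependence changed with microglia present. In CeA on control diet no gene passed in edgeR or DESeq2, and 726 of 11721 genes had an unadjusted edgeR p under 0.05. The smallest p belonged to Wwox at 0.45 ± 0.09 (edgeR adjusted p = 0.0643), the ubiquitin ligase scaffold Cul4b at -0.91, the acid-sensing channel Asic2 at 0.36, the glypican Gpc6 at 0.34 and the calcium-binding protein Cabp1 at 0.51. Effects went with gene length here as well, in a comparison that shares the control non-dependent libraries of the diet effect: genes spanning 100 kb or more had a median of 0.059 and shorter ones of -0.018 (Spearman rho of span and log2 fold change 0.158). In CeA comparisons of 2 groups without these libraries the sign was opposite. There rho was -0.137 for dependence on PLX5622 diet and -0.0671 for diet in dependent mice. Glucocorticoid response genes lay above 0 in 16 of 18 cases (median 0.36; camera adjusted p = 1.22e-06, and adjusted p = 0.398 with an estimated correlation), with the metallothionein Mt2 at 0.71 ± 0.23 and the clock gene Per1 at 0.38 ± 0.13. Meninges and choroid plexus genes had a median of -0.30 over 15 (adjusted p = 3.88e-05, and 0.536 with an estimated correlation), with the collagen gene Col3a1 at -2.74 ± 0.91. Neuropeptide and stress system genes had a median of 0.11 (adjusted p = 0.0480, and 0.370 with an estimated correlation), with Crh, the corticotropin-releasing hormone gene, at 0.97 ± 0.31 (5.03 ± 2.56 CPM, n = 6, to 9.65 ± 2.42, n = 5). As many list tests, 73, passed with DESeq2 size factors as with TMM factors. Immediate early genes here had an unadjusted camera p of 0.00470 with the former and 0.00496 with the latter. Camera at the preset correlation also called other lists as up, given here with DESeq2 size factors. These were pan-myeloid genes (adjusted p = 0.00392), interferon response genes (0.00558) and ion channels that ethanol targets (0.0227). Immediate early genes (0.0243) and glutamate receptor and synapse genes (0.0473) were among them too. None of these lists passed here with an estimated correlation. Each of 3 left-out libraries (control non-dependent 16 and 20, control dependent 9) gave 1 call.

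In mPFC on control diet dependence raised 1 gene, Jun (chromosome 4, 95049034 to 95052222), which encodes a subunit of the AP-1 transcription factor and is induced by neuronal activity and stress. It rose from 24.3 ± 3.52 CPM (SD, n = 7) to 35.3 ± 2.85 (n = 9) with no overlap, a log2 fold change of 0.55 ± 0.10 (edgeR adjusted p = 0.0104). The 3 dependent libraries with spike-in RNA had 34.7 ± 2.49 CPM and the 6 without 35.6 ± 3.19. Without the spiked libraries the log2 fold change was 0.57 ± 0.11 with an edgeR adjusted p of 0.0703, and without each of control libraries 19, 20, 34 and 35 the call was lost as well, with adjusted p up to 0.0922. DESeq2 also called 1 gene, and 2 were called by edgeR without control library 17 or 33. Immediate early genes as a group lay above 0 in 24 of 25 cases, with 1 past the threshold, 3 when adjusted over the list alone (camera adjusted p = 0.0343 with an estimated correlation). Among them were the phosphatase gene Dusp6 at 0.29 ± 0.09 and the synaptic scaffold gene Homer1 at 0.16 ± 0.05. Interferon response genes lay above 0 in 12 of 12 cases with none past the threshold, 2 adjusted over the list alone (camera adjusted p = 4.85e-05, and adjusted p = 0.102 with an estimated correlation), with Ifitm3 at 0.70 ± 0.20 and Irf9 at 0.51 ± 0.17. Other lists moved up alongside at the preset correlation and not with an estimated one, among them those with medians of 0.15 for glucocorticoid response genes (camera adjusted p = 0.00118, and 0.564 with an estimated correlation), 0.11 for oligodendrocyte genes (0.00525 and 0.764), 0.26 for striatal neuron genes (0.0156 and 0.789), 0.19 for central amygdala neuron genes (0.0156 and 0.555), 0.12 for mural cell genes (0.0207 and 0.436) and 0.090 for endothelial genes (0.0330 and 0.455). The pan-myeloid list mean was higher by 0.11 (exact two-sided permutation p = 0.0237, adjusted p = 0.0440), a call that was lost without control library 36, where the difference was 0.099. Set against all other genes by camera no shift of the list was detected (adjusted p = 0.772). Without the spiked libraries the difference was 0.16 (exact permutation p = 0.00641). Camera at the preset correlation, given here with DESeq2 size factors, also called activated microglia genes (adjusted p = 0.0108) and oligodendrocyte precursor genes (0.0472), both up. Neither list passed with an estimated correlation.

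**Figure D4:**
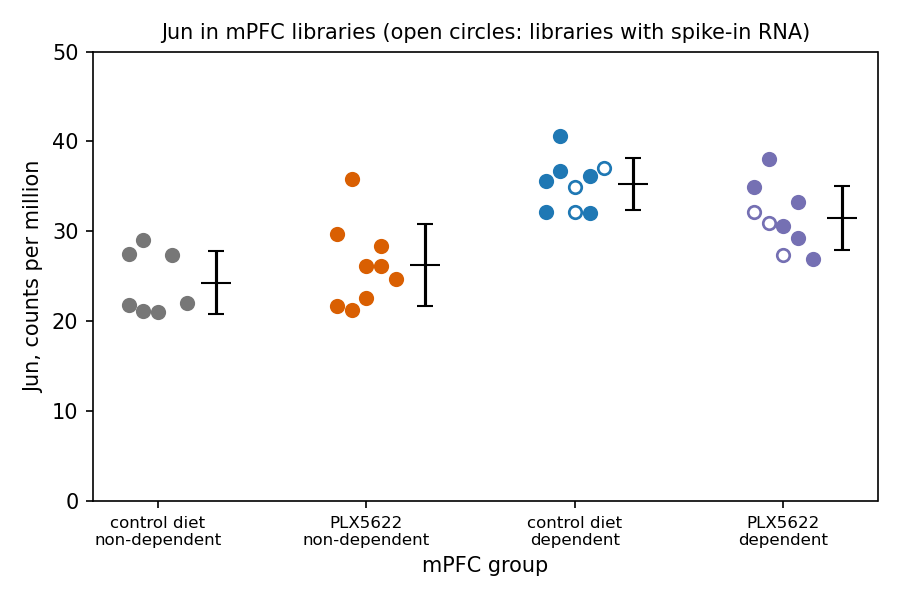
Jun in CPM for each mPFC library by group (points, open for libraries with spike-in RNA, with group mean and SD). Control dependent libraries lay between 32.1 and 40.6 and control non-dependent libraries between 21.0 and 29.1.

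With microglia depleted, dependence gave no call in either region. In CeA on PLX5622 diet edgeR and DESeq2 called 0 genes and 712 had an unadjusted edgeR p under 0.05. The smallest p belonged to the immediate early gene Fos, from 17.0 ± 3.25 CPM (SD, n = 4) to 37.8 ± 11.2 (n = 4), a log2 fold change of 1.14 ± 0.21 (edgeR adjusted p = 0.0641), then Rsrp1 at 0.54, Smoc2 at -1.17, Ftx at -0.49 and Cflar at -0.90. Immediate early genes lay above 0 in 21 of 24 cases, with none past the threshold and 5 when adjusted over the list alone (camera adjusted p = 1.83e-08, and adjusted p = 0.188 with an estimated correlation), with Btg2 at 1.01 ± 0.29. Their mean log2 fold change was 0.36, and -0.041 when only the 1 dependent library without spike-in RNA was kept. Meninges and choroid plexus genes had a median of -1.03 over 15 (adjusted p = 3.91e-11, and 0.220 with an estimated correlation), striatal neuron genes one of 0.65 over 13 (adjusted p = 0.000581, and 0.755 with an estimated correlation). The count was 4 without control non-dependent library 19, 2 without control non-dependent 14 or PLX5622 dependent 29, 1 without control non-dependent 16 or 17, and 3 when only these 2 groups entered.

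In mPFC on PLX5622 diet edgeR and DESeq2 called 0 genes, with 748 of 12331 at an unadjusted edgeR p under 0.05. The smallest p belonged to the apoptosis regulator Hrk at 0.38 ± 0.08, the peptide hormone gene Apln at -0.73, Rasl11b at 0.39, the calcium channel gene Cacna1g at -0.37 and the immediate early gene Egr4 at 0.30 ± 0.07 (45.0 ± 4.36 CPM to 55.5 ± 4.50, n = 9 each). Immediate early genes lay above 0 in 22 of 25 cases, none past the threshold and 9 when adjusted over the list alone (camera adjusted p = 0.0343 with an estimated correlation), with Nr4a1 at 0.47 ± 0.13. Jun was at 0.27 ± 0.09 (edgeR adjusted p = 0.623). Central amygdala neuron genes had a median of 0.18 (camera adjusted p = 0.00675, and 0.47 with an estimated correlation), oligodendrocyte genes of 0.089 (0.0156 and 0.789) and striatal neuron genes of 0.38 (0.0480 and 0.812). Without PLX5622 non-dependent library 16 or 21, or PLX5622 dependent library 8, 1 gene was called. Dependence effects on the 2 diets correlated across genes with r = 0.278 (jackknife SE 0.190) in CeA and r = 0.225 (SE 0.109) in mPFC.

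Whether depletion changed the response to dependence was tested as an interaction. No gene passed in either region by edgeR or DESeq2, with 553 of 11721 genes in CeA and 375 of 12331 in mPFC at an unadjusted edgeR p under 0.05. The smallest p in CeA belonged to Ehmt1 at -0.65 ± 0.15, Gpc6 at -0.50, Ggct at 0.87, Fam155a at -0.49 and Smoc2 at -1.23, with a median of -0.088 for genes spanning 100 kb or more and 0.030 for shorter ones (Spearman rho -0.225). In mPFC they belonged to Cog7 at -0.52 ± 0.12, Gla at 1.03, H2-T23 at -1.03, Hnrnph2 at 0.90 and the smooth muscle actin gene Acta2 at -1.43. In mPFC mural cell genes had a median of -0.33 over 9 (camera adjusted p = 0.000581, and adjusted p = 0.154 with an estimated correlation), 2 lower when adjusted over the list alone, meninges and choroid plexus genes one of -0.40 over 7 (adjusted p = 0.000868, and 0.455 with an estimated correlation), endothelial genes one of -0.16 over 18 (adjusted p = 0.00525, and 0.261 with an estimated correlation) and interferon response genes one of -0.19 over 12 (adjusted p = 0.00525, and 0.329 with an estimated correlation). In CeA the lists with the smallest p were interferon response genes with a median of -0.68 over 8 (camera adjusted p = 0.00675, and 0.570 with an estimated correlation), oxidative phosphorylation genes with 0.075 over 25 (adjusted p = 0.0124, and 0.60 with an estimated correlation) and immediate early genes with 0.16 over 24 (adjusted p = 0.0156, and 0.726 with an estimated correlation). The Jun effect on control diet is thus not shown to differ from that on PLX5622 diet.

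A difference of effects between the regions was tested in 1 fit of all 8 groups. The diet effect differed for 7 of 13035 genes in edgeR and 25 in DESeq2. For Ptprc, the leukocyte common antigen CD45, the log2 diet effect in CeA minus that in mPFC was 2.66 ± 0.35 (edgeR adjusted p = 3.73e-07). Its diet effect in CeA was -0.081 in non-dependent and 0.0035 in dependent mice. The 17 pan-myeloid genes tested there had medians of -3.28 and -3.41. What the CeA counts of Ptprc stem from was not tested. In mPFC it went from 2.74 ± 0.79 and 3.52 ± 0.73 CPM (SD, n = 7 and 9) to 0.42 ± 0.34 and 0.43 ± 0.60 (n = 9 each), in CeA from 9.42 ± 2.39 and 10.3 ± 1.28 (n = 6 and 5) to 8.80 ± 3.27 and 10.5 ± 2.70 (n = 4 each). The other genes were Nell1 at 0.41 ± 0.07, Spink10 at 0.65, the stress kinase Mapkapk2 at 0.79, Ppm1l at 0.30, Cdc42ep3 at -0.57 and the nuclear envelope gene Sun2 at -0.68. The gene models of Spink10 and Cdc42ep3 differ in version between the counts of the 2 regions. Without 1 library at a time the call of Sun2 was lost in 23 of 53 fits, that of Ppm1l in 5 and that of Cdc42ep3 in 4. With the mouse number as a fixed block over mice with both regions by that number 10 genes passed, and Mapkapk2, Ppm1l, Cdc42ep3 and Sun2 did not (edgeR adjusted p = 0.0940, 0.0940, 0.107 and 0.0940), nor did they in the same mice without the block (0.108, 0.125, 0.125 and 0.104). The count was 13 without CeA control non-dependent 14 or 16, 4 without CeA control non-dependent 19, CeA PLX5622 non-dependent 47 or CeA control dependent 11, 11 without CeA PLX5622 non-dependent 13 or CeA control dependent 3, 18 without CeA control dependent 1 or CeA PLX5622 dependent 6, and 14 without mPFC PLX5622 non-dependent 21. Dependence effects differed between regions for 0 genes on either diet in edgeR and DESeq2, with 637 and 613 genes at an unadjusted edgeR p under 0.05. The smallest p belonged to Cabp1 at 0.58, Amigo1 at -0.67 and Hdac8 at 0.37 on control diet, and to Polr2h at 0.86, Pcbp4 at 0.53 and Psmd6 at 0.61 on PLX5622 diet.

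The regions themselves differed widely in control non-dependent mice, in a comparison that also holds the instrument, dissection and annotation release. Central amygdala neuron genes were higher in CeA in 17 of 22 cases and lower in 1, with the neuropeptide gene Nts at 6.05 ± 0.51, the transcription factor Nr2f2 at 3.03 and the retinoic acid enzyme Cyp26b1 at 2.53. Excitatory cortical neuron genes were higher in mPFC in 13 of 19 cases and in CeA in 5, with Tbr1 at -1.82 and Mef2c at -1.16. Striatal neuron genes were higher in CeA in 13 of 15 cases, oligodendrocyte genes in 15 of 23, and meninges and choroid plexus genes in 11 of 16, with the choroid plexus gene Ttr at 13.33 ± 0.93. Immediate early genes were higher in mPFC in 14 of 25 cases and circadian clock genes in 10 of 16, with 2 higher in CeA in each list. Among the smallest p were those of Ndfip1 at 2.40, Romo1 at 4.02, Ncdn at 1.22 and Fads2 at 3.83 among genes higher in CeA, and of Hnrnpul2 at -4.02, Ube2d2a at -2.57 and Fam173a at -6.04 among genes higher in mPFC. Csf1r was higher in CeA by 0.40 and Tmem119 by 0.53. In all 6076 of 13035 genes passed in edgeR, 3042 higher in CeA and 3034 higher in mPFC. In mice with both regions the count was 4004 with the mouse number as a block and 4014 without it.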

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

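The tests of the drinking history and of the reference libraries for the CeA genes higher with PLX5622, and of both regions for the immediate early genes, were chosen only after the result was seen, as was the dependence effect over both diets.

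Single libraries lay far from the rest of their group in 11 of the groups of values tested, where chance alone marks about 1 in 20 groups, or 6.2 of them. In CeA, control dependent library 2 had a border macrophage mean of 3.07 (others 1.49 to 1.63) and P2ry12 at 43.6 CPM (others 24.7 to 28.2). Control non-dependent library 16 had 1749531 counts in genes (others 1242295 to 1393991) and 18362 genes detected (others 17562 to 17711). PLX5622 dependent library 29 had an immediate early gene mean of 4.41 (others 4.82 to 4.89), and PLX5622 non-dependent library 13 had 1385746 counts in genes (others 1527158 to 1550210). In mPFC, PLX5622 dependent library 30 had a homeostatic microglia mean of 2.27 (others 1.43 to 1.81), a pan-myeloid mean of 2.18 (others 1.07 to 1.37), Tmem119 at 4.32 CPM (others 0 to 1.82) and Cx3cr1 at 10.6 CPM (others 1.53 to 5.10). PLX5622 dependent library 37 had an oligodendrocyte mean of 4.92 (others 5.26 to 5.61).

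A test of the difference between regions set apart the diet effect of 7 genes, on the log2 scale in CeA minus mPFC: Ptprc at 2.66, Nell1 at 0.41, Spink10 at 0.65, Mapkapk2 at 0.79, Cdc42ep3 at -0.57, Ppm1l at 0.30 and Sun2 at -0.68. Spike-in RNA, kept out of library sizes and of the main tests, was at 11745 counts or more in the CeA libraries that held it (others 85 to 316) and at 21989 or more in those of mPFC (others 0 to 69).

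Regrouping the same libraries at random tells whether chance alone could give as many calls. It can be excluded for the diet effect in CeA of non-dependent mice (50 genes up and 57 down, and at most 37 in all in the other of 100 splits), in CeA of dependent mice (48 and 20), in mPFC of non-dependent mice (78 and 3) and in mPFC of dependent mice (0.92% of the genes tested, and 58 genes). In each of these comparisons the real grouping was the only 1 as large. The splits counted genes up and down together, and the 57 down alone exceed 37. Chance is thus not excluded for the 50 genes up in CeA of non-dependent mice taken by themselves, nor for the genes up in the other diet comparisons. The real grouping was also the only 1 as large for dependence in mPFC over both diets (27 and 23), an effect chosen after results were seen. It was so too for the diet effect between regions (7 and 5 over 40 splits) and for the regions (6076 and 2213 over 40 splits). For the first 2 of these a regrouping came close to the real count, so chance is not excluded for them. For dependence in mPFC on control diet 2 of 100 splits were as large, the real one included (1 and 2). A regrouping called more genes there than the real groups, so chance cannot be excluded for that 1 call. Nor can chance be excluded for dependence over both diets in CeA (3 and 17, with 5 of 100 splits as large). Why a regrouping there called several times the real count was not tested. Where edgeR called 0 genes every split is as large by definition, so regrouping cannot tell anything about chance there. These were 100 of 100 for dependence in CeA on control diet (highest other 8) and for the CeA interaction (1), 35 of 35 for dependence in CeA on PLX5622 diet (0), 100 of 100 for dependence in mPFC on PLX5622 diet (4) and for the mPFC interaction (3), and 40 of 40 for the differences of dependence between regions on control diet (6) and PLX5622 diet (0).

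In CeA of non-dependent mice 50 genes rose with PLX5622, 47 of them spanning 100 kb or more. When single reference libraries were left out, as few as 24 rose, and without PLX5622 library 23 only 19, so a low share of long genes in some reference libraries stays open as an explanation; the comparison with the PLX5622 libraries was added after the value was seen. With the level of long genes as a covariate 12 of the 50 stayed called (median log2 fold change 0.38 before and 0.32 after, median SE 0.085 and 0.089). Length bias between libraries stays open: over the 13 libraries of the other groups the genes followed other long genes with r = -0.0186, above the 95th percentile of -0.208 of 1000 random sets of shorter genes as the test set beforehand asked, but with an r near 0, and a need for r above 0 was added after the value was seen. The random sets themselves had a median r of -0.589, so passing their 95th percentile says little. The test used deviations within groups and so could not show a shift between groups. In dependent mice the same genes were higher by 0.0904 with PLX5622 (exact two-sided permutation p = 0.0873), against 0.40 in non-dependent mice. A diet effect whatever the history thus stays open as well.

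Immediate early genes were higher with dependence in mPFC on both diets. A batch of libraries with spike-in RNA and striatal tissue in the dissection are both argued against, since the mean log2 fold change without the spiked libraries was at least 1.01 times, and with the striatal covariate at least 0.952 times, the main value on either diet. An effect of dependence in both regions stays open, with an exact two-sided permutation p of 0.114 as the smaller of the 2 diets in CeA. Without the spiked libraries the mean log2 fold change of the list in CeA went from 0.36 to -0.041 on PLX5622 diet, with 1 dependent library left. On control diet it went from 0.14 to 0.088. In CeA the shift thus cannot be told apart from the spiked libraries. Stress or handling that differed between the groups was not tested.

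Between the regions 6076 genes differed. Different annotation releases could account for part of the large differences, since genes whose model version differs passed with 4-fold or more 4.21 times as often (5.36% against 1.27%, two-sided Fisher exact p = 7.36e-18). They are argued against as the whole cause, since 46.9% of the genes with the same version passed. Neuron types of the regions stay open: of the list members that passed, 94.4% of central amygdala genes were higher in CeA and 72.2% of excitatory cortical genes higher in mPFC, under the share set beforehand. Instrument and dissection go with region and cannot be told apart from it.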

How the results depend on the processing

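The libraries without spike-in RNA, the covariates for spike-in RNA, striatal genes and long genes, the fit of the same mice without a block, and the dependence effect over both diets were chosen only after results were seen. Of the genes called and named, 1 was no longer past the threshold with DESeq2 size factors, 4 with 1 surrogate variable, 4 with no filter, 9 with DESeq2 and 16 in at least 1 fit that left out 1 library. Of those tested, 89 of 94 stayed at a mean CPM of 5 or more, 69 of 77 with only the 2 groups, 88 of 90 with the spike-in covariate, 86 of 90 with the striatal covariate and 76 of 90 without spiked libraries, with 0 turning direction. At the depth reached, 42% of 1.5-fold diet effects in CeA of non-dependent mice were recovered in simulation, so effects of that size are often missed. The cause of the changes below was not tested, except where fewer genes or libraries entered.

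Numbers of called genes are given here as percent of the genes in the main test (11721 in CeA, 12331 in mPFC, 13035 jointly), whatever the setting tested. With no filter on low counts edgeR called, in the order diet in non-dependent and dependent mice, dependence on control and PLX5622 diet, 2.18%, 0.913%, 0.196% and 0.085% in CeA and 1.39%, 1.72%, 0.024% and 0.057% in mPFC, 0.0085% for the interaction in CeA, and 1.3%, 0.138% and 0.153% for the region differences of the diet effect and of dependence on the 2 diets. At a mean CPM of 5 or more, with fewer genes tested, the diet effects in mPFC gave 0.405% and 0.60%, and the correlations of diet effects were 0.693 between histories in mPFC and 0.543 and 0.576 between regions in non-dependent and dependent mice. DESeq2 gave 1.18% and 1.47% for diet in mPFC and 0.192% for the region difference of the diet effect. With only the 2 groups compared, and so fewer libraries, diet gave 0.572% in non-dependent CeA and 0.584% in dependent mPFC, and dependence on PLX5622 diet in CeA gave 0.026%. With 1 surrogate variable dependence on control diet in mPFC gave 0.016%. Without spiked libraries diet in dependent CeA gave 0.179%, and dependence on control diet in mPFC and over both diets in CeA 0%. There the homeostatic microglia mean differed by -2.31 and the pan-myeloid mean by -2.30 in dependent CeA, and the mean log2 fold change of immediate early genes with dependence on PLX5622 diet in CeA turned to -0.041. For dependence on control diet in CeA the spike-in covariate gave 0.0085% and the striatal covariate 0.034%. The border macrophage mean in non-dependent CeA was -0.79 with a pseudocount of 0.25 (exact permutation p = 0.0667). Of 310 list tests 73 passed, 11 with an estimated correlation and 15 with fry.

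With the mouse number as a fixed replicate block, in mice with both regions, 10 genes were called for the region difference of the diet effect, 0 and 0 for those of dependence and 4004 (30.7%) for the regions, where the same mice gave 4014 (30.8%) without it. With a random block in limma voom they were 8, 0, 0 and 6025. In these mice Mapkapk2, Ppm1l, Cdc42ep3 and Sun2 were no longer called, with the fixed block and without it, so these losses and the lower count between regions came with fewer mice. In limma voom with the random block Sun2 was not called, and no other call of a gene named changed. Voom without a block was not run, so the loss of Sun2 cannot be assigned to the block or to the test. Without the 2 libraries numbered 16 the region difference of the diet effect gave 0.0997%.

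Leaving out 1 library at a time gave, in the order above, 0.597% to 1.13%, 0.375% to 0.478%, 0% to 0.0085%, 0% to 0.034% and for the interaction 0% to 0% in CeA, and 0.592% to 0.673%, 0.762% to 0.957%, 0% to 0.016%, 0% to 0.0081% and 0% to 0% in mPFC. It gave 0.031% to 0.138%, 0% to 0%, 0% to 0% and 43.8% to 47.1% between regions. Homeostatic microglia means differed with diet by -2.16 to -2.01 and -2.22 to -2.14 in CeA and by -2.18 to -2.14 and -2.21 to -2.10 in mPFC, pan-myeloid means by -1.97 to -1.83, -2.08 to -1.94, -2.09 to -2.03 and -2.20 to -2.06, and border macrophage means by -0.69 to -0.38, -1.10 to -0.71, -1.0 to -0.90 and -1.15 to -0.95. With dependence on control diet in mPFC the pan-myeloid mean differed by 0.097 to 0.14.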

Other observations

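The dependence effect averaged over both diets and the comparison of microglial RNA within mice were chosen only after the results were seen. Averaged over the diets, dependence changed 27 of 12331 genes in mPFC, 19 up and 8 down (edgeR adjusted p under 0.05), and without the spiked libraries 27, of which 19 were shared. The apoptosis regulator Hrk rose by 0.37 ± 0.06 (SE), Jun by 0.41 ± 0.07, Dleu7 by 0.51, Plcxd2 by 0.26, Pmepa1, a brake on TGF-beta signalling, by 0.21, and the immediate early gene Egr4 by 0.25. The splicing factor gene Srsf3 fell by 0.28 ± 0.05, the complement inhibitor Susd4 by 0.17 and the globin gene Cygb by 0.27. Rasl11b rose by 0.33 and Fbxo9 fell by 0.23, calls lost without the spiked libraries (edgeR adjusted p = 0.0719 and 0.0774) while the log2 fold changes stayed at 0.29 and -0.19. In CeA 3 of 11721 genes rose, Rsrp1 by 0.40, Serp2 by 0.43 and Fos by 0.79 ± 0.14. None passed without the spiked libraries (0 genes in edgeR, 724 at an unadjusted p under 0.05), where Fos was at 0.38 (edgeR adjusted p = 0.918), Rsrp1 at 0.33 and Serp2 at 0.55 (edgeR adjusted p = 0.0585). DESeq2 was not run on these averages.

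Of the 41 genes that fell with PLX5622 in all 4 comparisons, 15 lie outside the microglia and macrophage lists. They were the transporter genes Abca9 and Slco2b1, the signalling genes Apbb1ip, Arhgap45, Dock2, Dock8, Fyb, Lyn, Ncf1 and Nckap1l, the transcription factor gene Runx1, the integrin gene Itgb5, and Hpgds, Il6ra and Mpeg1. In 8 PLX5622 mice taken as the same in both regions from their numbers alone, the homeostatic microglia means of CeA and mPFC correlated with r = 0.511 (exact two-sided permutation p = 0.196), and with r = -0.0669 without the 2 mice farthest from the rest.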
